A study of Drosophila melanogaster with 4 samples.

How the data were processed

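HP1b ChIP libraries (2) and Input libraries (2) from Drosophila melanogaster Oregon-R embryos of 14 to 16 h were grouped by the sample titles. Chromatin was fixed with formaldehyde and precipitated with antibody Q4114, per the labels. Reads were mapped with Bowtie 0.12.7, per the submitters' processing notes, and the coordinates are on FlyBase release 5, per the file headers. The program that called enriched regions, its threshold, the handling of reads that fit several places and the way the series-wide list was made from the replicates are not given in the sources used here. Per the labels, each Input library was the reference for the ChIP library with the same replicate number; no list of regions was analysed for the Input libraries.

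The deposited lists hold 1 score per region, whose definition is not given in the sources used here. Its scale was tested from the values. Within each list, 2 raised to the difference from the highest score is a ratio of whole numbers (denominator up to 2000, relative tolerance 1e-12) for 61.0% of the scores of replicate 1, 69.6% of replicate 2 and 55.3% of the series-wide list. With a natural or base 10 logarithm the share was at most 0.43%. The scores therefore step like a log2 ratio with a constant scaling, and a difference of 1 in score is read as a factor of 2 in the underlying ratio; the zero point and the normalization stay unknown. Scores were used to describe, rank and filter regions within a list, and to correlate the lists. The replicate lists have a shortest region of 1301 bp and the series-wide list one of 1001 bp, so the series-wide list does not have the minimum width of the replicate lists. No list holds read counts, so the depth per sample is unknown. Wilson intervals (95%) are given for shares of regions; they treat regions as independent and cover counting error only.

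All values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots with matplotlib 3.10.9. Regions were called shared when they overlapped by at least 1 bp. The reproducible set is the series-wide regions that overlap a region of both replicates; it keeps the series-wide boundaries, which can be wider than those of either replicate. The overlap of the replicates was compared with 1000 circular shifts of replicate 2 within each chromosome arm (one-sided permutation test). Cover is the percent of bases in regions, over the sequence lengths in the file headers. Arms and ends of arms were compared in bins of 100 kb (a last bin under 50% of this size was dropped) with a two-sided permutation test of the difference in means (100000 permutations), adjusted by Benjamini-Hochberg over the 6 arms. Each major arm was compared with the 4 others, and chromosome 4 with all 5. The centromeric end was the 1 Mb at the end of 2L, 3L and X and at the start of 2R and 3R. Score means of X and of chromosome 4 were compared by the same permutation test over regions. Shares found again were compared by Fisher's exact test, two-sided. For X they were also compared at matched score, within 10 strata of equal numbers of major arm regions ranked by score, weighted by the number of X regions, with normal 95% intervals.

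The tests of replicate overlap, score agreement, the series-wide list, the arms, the centromeric ends and the heterochromatin scaffolds, the samples and the rule for named regions were set before the data were examined. The rule took the 20 reproducible regions with the highest series-wide score, the top 2 of each of 2L, 2R, 3L, 3R, 4 and X, and the 5 widest. Gene lists, promoter overlap and genomic features were also planned, but the gene table at hand is of release 6 and its coordinates do not apply to release 5. These results, and the rule's part on genes, were therefore left out, and regions are given by position. Alternatives were the 50% of each list with the highest scores, overlaps of 50% of the shorter or of both regions, random placement or local shifts of 20 to 200 kb as the null, equal numbers of regions per replicate, each replicate alone, the whole series-wide list, regions per Mb, bins of 250 kb, 2 Mb at the centromeric end, arms without the centromeric 1 Mb, the centromeric comparison without each arm and series-wide regions at least as wide as the narrowest replicate region. For score agreement they were pairs that are each other's largest overlap, and pairs outside the heterochromatin and unplaced scaffolds. The local shifts, the trimmed arms, the left-out arms, the equal numbers in heterochromatin and the minimum width of series-wide regions were chosen after seeing the data, as were the tests of mean scores, the Fisher's exact tests, the division of the lists by rank of score, the shares found again at matched score and some tests of the closing section, which are named there.

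The procedures were tested on simulated data. When 50% or 80% of the 5248 replicate 1 regions were kept and the others placed at random, the overlap found was 54.5% and 80.8%, against 54.1% and 80.7% computed from the kept share. When none was kept, the overlap of 17.9% met the mean of the circular shifts, 18.0%. The bin test called 0 of 20 pairs of simulated arms of equal density and 20 of 20 in which 70% of the regions of 3L were kept (230 and 245 bins). The simulated regions of the bin test were placed at random, while the real regions lie in groups along the arms. The simulation therefore does not show the error rate for real bins, whose neighbours are not independent. The p-values of all bin tests may be too small.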

Results

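HP1b is a member of the Heterochromatin Protein 1 family, chromodomain proteins of Drosophila chromatin. Its genomic binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in Drosophila melanogaster embryos of 14 to 16 h, a late stage at which organs differentiate, from Oregon-R, a standard wild-type laboratory strain. The 4 samples comprised 2 HP1b ChIP libraries (replicates 1 and 2, antibody Q4114) and 2 Input libraries, each of which served as the reference of the ChIP library with the same number. The measurement analysed here is the list of enriched regions of each ChIP replicate and a list for the series as a whole. Replicate 1 had 5248 regions covering 12.8 Mb, with a median width of 2176 bp and a shortest region of 1301 bp. Replicate 2 had 4633 regions covering 10.7 Mb, with a median width of 2121 bp and the same shortest width. The series-wide list had 9130 regions covering 20.7 Mb, with a median width of 1999 bp and a shortest region of 1001 bp. Each region carried a score from the authors, and the read depth behind it is unknown because the lists hold no counts. The labels do not say whether the replicates came from separate embryo collections, so the spread between them may be technical.

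HP1b regions recurred at the same positions in both replicates. Of the replicate 1 regions, 74.5% (3910 of 5248) overlapped a replicate 2 region by at least 1 bp, against a median of 16.4% and a maximum of 19.7% when replicate 2 was shifted circularly within each chromosome arm. Of the replicate 2 regions, 85.9% (3982 of 4633) overlapped a replicate 1 region, against a median of 18.6% under the shifts. Both shares exceeded all 1000 shifts (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The covered bases of the replicates had a Jaccard index of 0.638, against a median of 0.049 over 100 shifts. Regions found in only 1 replicate were weaker. The 1338 replicate 1 regions without a partner had a median score of 0.52, against 0.80 for those with one, and the 651 replicate 2 regions without a partner had a median of 0.62, against 0.77. The share of replicate 1 regions found again rose from 48.9% of the 1312 lowest-scoring to 97.0% of the 1312 highest-scoring (95% Wilson intervals 46.2 to 51.6% and 95.9 to 97.8%). In replicate 2 it rose from 75.2% of the 1159 lowest-scoring to 97.8% of the 1158 highest-scoring regions (95% Wilson intervals 72.6 to 77.6% and 96.8 to 98.5%). Across the 3910 overlapping pairs, which are not independent replicates, the scores of the replicates correlated with a Spearman rho of 0.833 and a Pearson r of 0.889.

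**Figure D1:**
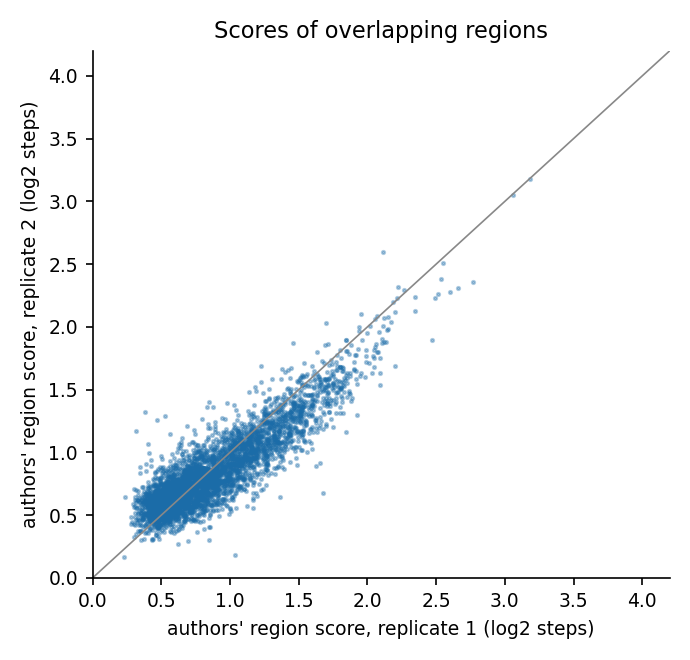
Authors' region scores of the 3910 replicate 1 regions (x axis) against the replicate 2 region each overlaps most (y axis), 1 point per pair, with the line of equal scores. Scores rise together (Spearman rho 0.833 across regions); the zero point of each list is unknown, so distances from the line are not read.

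The series-wide list held nearly every replicate region and many more. It contained 99.6% of the replicate 1 regions and 98.8% of the replicate 2 regions. Of its own 9130 regions, 3829 (41.9%, 95% Wilson interval 40.9 to 43.0%) overlapped regions of both replicates and are called the reproducible set below. Another 1260 (13.8%) overlapped replicate 1 alone and 561 (6.14%) replicate 2 alone. The remaining 3480 (38.1%) overlapped neither. These 3480 regions were narrow, with a median width of 1289 bp against 2617 bp in the reproducible set, and had a median score of 0.40 against 0.71. Part of this follows from the lists themselves, since 1786 of the 3480 are narrower than 1301 bp, the shortest region of either replicate list. The make-up of the series-wide list differed by chromosome. On the 5 major arms (2L, 2R, 3L, 3R and X) 33.9% of its regions overlapped neither replicate. On the assembled heterochromatin scaffolds, which hold sequence next to the centromeres and from the Y, the share was 68.7% (439 of 639). On U, a collection of unplaced sequence, it was 74.1% (249 of 336). Among the 7224 series-wide regions of at least 1301 bp, 53.0% overlapped both replicates, and the shares in neither were 20.8% on the major arms, 52.3% on the heterochromatin scaffolds and 53.4% on U. The 6 series-wide regions on YHet overlapped no replicate region, and no list had a region on Uextra.

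**Figure D2:**
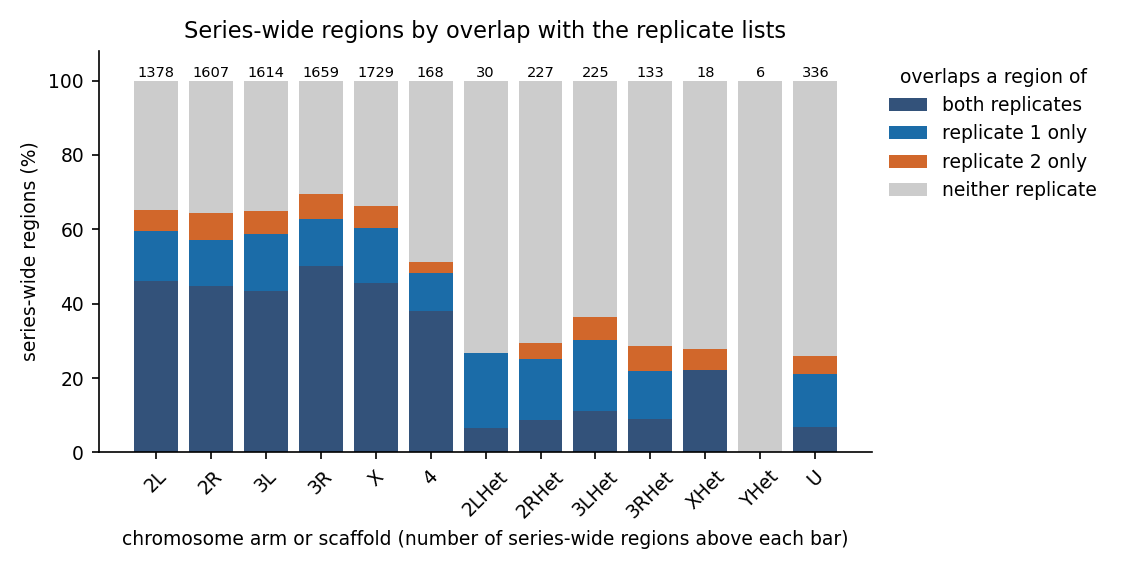
Share of series-wide regions (y axis, %) on each chromosome arm or scaffold (x axis) that overlap regions of both replicates, of 1 replicate or of neither, with the number of regions above each bar. Between 30.6% and 35.7% of the regions on the major arms overlapped neither replicate, 48.8% did so on chromosome 4, and 63.6% or more on each heterochromatin scaffold and on U.

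**Figure D3:**
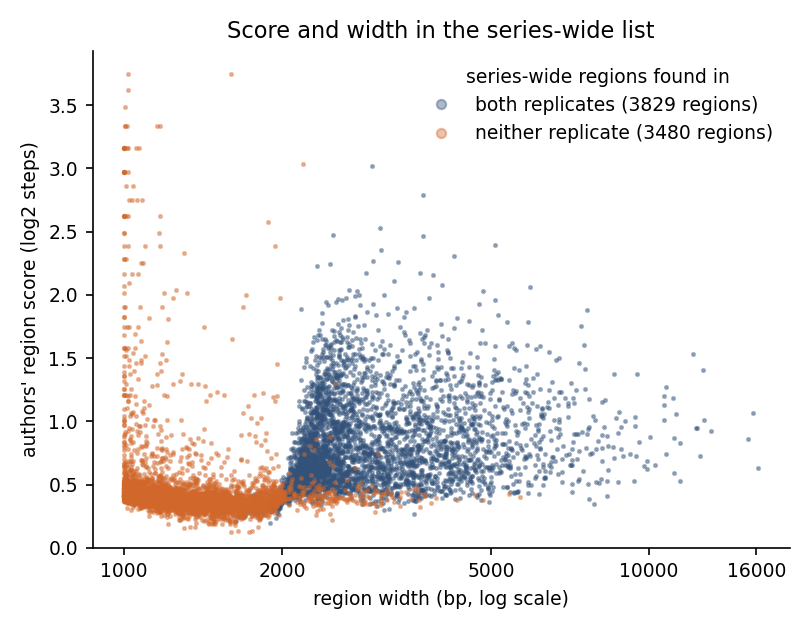
Authors' score (y axis, log2 steps) against width (x axis, bp, log scale) of the series-wide regions that overlap regions of both replicates (3829 points) or of neither (3480 points). The regions of neither replicate are narrow, with a median of 1289 bp against 2617 bp, and some of the narrowest carry the highest scores, up to 3.75.

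The first question on location was whether HP1b was spread evenly over the chromosomes. Chromosome 4, the small and largely heterochromatic autosome, was the most densely covered. HP1b regions covered 19.1% of it in replicate 1 and 14.5% in replicate 2 (16.8% ± 3.23, SD, n = 2), against 10.1% and 8.60% of the 5 major arms together (9.33% ± 1.03, SD, n = 2). In the reproducible set 22.2% of chromosome 4 was covered, by 64 regions. This set keeps the series-wide boundaries, which are wider on chromosome 4 and raise its cover. The median width there was 3725 bp, against 2254 bp in replicate 1 and 2020.5 bp in replicate 2. On the autosomal arms it was 2561 bp, against 2184.5 bp and 2126 bp. The mean cover of 100 kb bins was 21.7% on chromosome 4 (14 bins) and 9.60% on the major arms, a difference of 12.1 percentage points (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give, Benjamini-Hochberg adjusted p = 3e-05 over 6 arms). The difference was 8.50 points with replicate 1 regions alone (adjusted permutation p = 0.00024) and 5.54 points with replicate 2 regions alone (adjusted permutation p = 0.00798). Chromosome 4 regions were weak. Their mean score in the reproducible set was 0.61, against 0.81 on the major arms (permutation p = 2e-05), and the mean was also lower in replicate 1 (0.70 against 0.81, permutation p = 0.00764) and in replicate 2 (0.68 against 0.83, permutation p = 3e-05). Neighbouring regions are not independent, so these p-values may be too small. The lists share regions, so these score tests are not separate results. With only the 50% of each list that scored highest, cover was 8.18% on chromosome 4 and 5.55% on the major arms, a difference of 2.63 points that did not pass the threshold (adjusted permutation p = 0.103).

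The X chromosome was covered more than the large autosomal arms. HP1b regions covered 12.5% of X in replicate 1 and 10.5% in replicate 2 (11.5% ± 1.40, SD, n = 2), against 9.50% and 8.16% of the autosomal arms 2L, 2R, 3L and 3R (8.83% ± 0.948, SD, n = 2). The ratio of X to autosomal cover was 1.31 in replicate 1, 1.28 in replicate 2 and 1.33 in the reproducible set. In 100 kb bins of the reproducible set, X exceeded the autosomal arms by 2.93 percentage points (12.0% against 9.05%, permutation p = 1e-05, adjusted p = 3e-05). X regions also scored higher. Their mean score exceeded that of autosomal regions by 0.10 in replicate 1, 0.12 in replicate 2 and 0.11 in the reproducible set (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Without regard to score, 75.1% of replicate 1 and 87.4% of replicate 2 regions on X were found again, against 77.0% and 86.7% on the autosomal arms. At matched score, a comparison chosen after these values were seen, X regions were found again less often, by a difference of -8.85 percentage points in replicate 1 (95% interval -11.2 to -6.50) and -3.70 points in replicate 2 (95% interval -5.91 to -1.49). The definition of the score is unknown, so equal scores on X and on the autosomal arms need not mean equal enrichment. Among the autosomal arms, 2R was covered most, with 10.2% ± 1.01 (SD, n = 2), and 2L least, with 8.14% ± 0.952 (SD, n = 2). In the reproducible set 2R lay 1.39 points above the other major arms (adjusted permutation p = 0.0273), 2L differed from them by -1.53 points (adjusted permutation p = 0.0197) and 3L by -1.36 points (adjusted permutation p = 0.0271), while 3R, at 8.79% against 9.85%, did not pass the threshold (adjusted permutation p = 0.0541). The other major arms include X in each case. Part of the lower values of 2L, 3L and 3R therefore restates the higher cover of X, and the excess of 2R is understated. Mean bin cover was 8.37% on 2L, 10.7% on 2R, 8.52% on 3L and 8.79% on 3R, against 12.0% on X. Tests among the autosomal arms alone were not run. The calls against the other major arms depended on the setting. Of 8 alternatives, all with X in the reference of each autosomal arm, 5 ended the call for 2R and 4 that for 3L, and 4 called 3R lower than this reference. With replicate 1 regions alone, for example, the adjusted permutation p was 0.0806 for 2R, 0.103 for 3L and 0.0298 for 3R. Neighbouring bins and regions are not independent, so these p-values may be too small. The score tests of X in the replicates and the reproducible set share regions and are not separate results.

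**Figure D4:**
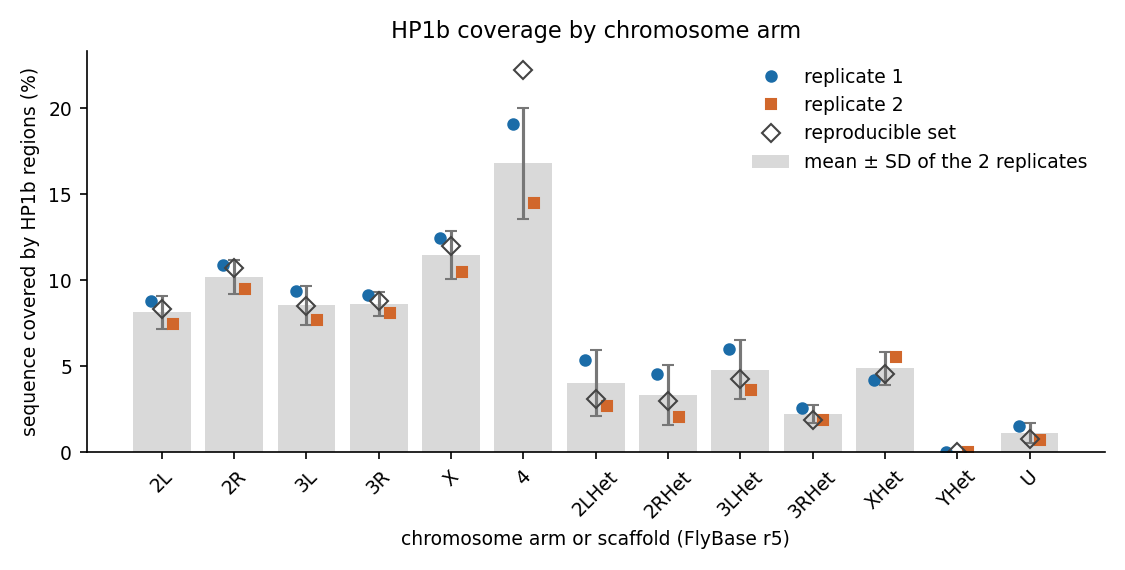
Percent of each chromosome arm or scaffold covered by HP1b regions (y axis) in replicate 1 (circles), replicate 2 (squares) and the reproducible set (diamonds), with grey bars for the mean and error bars for the SD of the 2 replicates. Chromosome 4 has the highest mean at 16.8%, X follows at 11.5%, and the heterochromatin scaffolds and U lie below 5%.

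The second question on location was how HP1b regions divided between the arms and assembled heterochromatin. The heterochromatin scaffolds (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet, 9.28 Mb in all) were covered less than the major arms. Cover was 4.28% in replicate 1 and 2.47% in replicate 2 (3.38% ± 1.28, SD, n = 2). In the reproducible set the scaffolds held 63 of the 3829 regions, and their 100 kb bins were covered 6.64 percentage points less than those of the major arms (2.95% against 9.60%, permutation p = 1e-05). The difference was smaller in the whole series-wide list, at -2.81 points (12.7% against 15.5%, permutation p = 0.0115). Within heterochromatin 3LHet had the highest cover among the scaffolds over 1 Mb, with 4.82% ± 1.69 (SD, n = 2), and 3RHet the lowest, with 2.23% ± 0.520 (SD, n = 2). Regions in heterochromatin recurred less often. Of the 177 replicate 1 regions there 36.7% were found in replicate 2, against 76.6% of the 4899 on the major arms (two-sided Fisher's exact p = 2.6e-28). For replicate 2 the shares found in replicate 1 were 61.5% of 109 and 86.8% of 4397 (Fisher's exact p = 6.8e-11). Both tests count largely the same overlaps (65 replicate 1 and 67 replicate 2 regions in heterochromatin), so they are not separate results. Fewer regions and lower cover in heterochromatin also leave fewer overlaps to be found, and the tests do not adjust for this. Cover was computed over the full scaffold length, assembly gaps included, and reads that fit several repeat copies may have been treated differently there by the mapping, which the sources used here do not describe.

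Within the major arms the 1 Mb at the centromeric end was compared with the rest of the arm. The arms did not share a direction. On 2R the centromeric 1 Mb was covered 16.0% in replicate 1 and 9.99% in replicate 2, against 10.7% and 9.48% of the rest of the arm. On X it was covered 5.24% and 3.57%, against 12.8% and 10.8%. On 3L it was covered 6.31% and 3.32%, against 9.50% and 7.92%. On 3R it was covered 9.30% and 8.71%, against 9.13% and 8.10%. On 2L the replicates differed in direction, with 9.59% and 7.18% against 8.78% and 7.48%. Over the 5 arms of the reproducible set, cover was 7.75% in the centromeric 1 Mb and 9.69% elsewhere, and the difference of -1.93 percentage points did not pass the threshold (permutation p = 0.0934). Single arms and replicates moved it: it was -0.284 points without X (permutation p = 0.815), -3.40 points without 2R (permutation p = 0.00896), -0.819 points with replicate 1 alone (permutation p = 0.456) and -2.14 points with replicate 2 alone (permutation p = 0.0287). Counted as regions per Mb, the centromeric 1 Mb was lower, with 19.4 against 31.4 (permutation p = 0.00064). In the whole series-wide list the direction turned, with 22.2% covered in the centromeric 1 Mb and 15.3% elsewhere (permutation p = 1e-05). By arm the series-wide difference was 22.3 points on 2R, 12.8 on 2L, 5.18 on 3L, 1.79 on 3R and -8.14 on X. Bins were pooled over the arms, and neighbouring bins are not independent. The permutation p-values given here may thus be too small and do not measure the spread between arms.

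**Figure D5:**
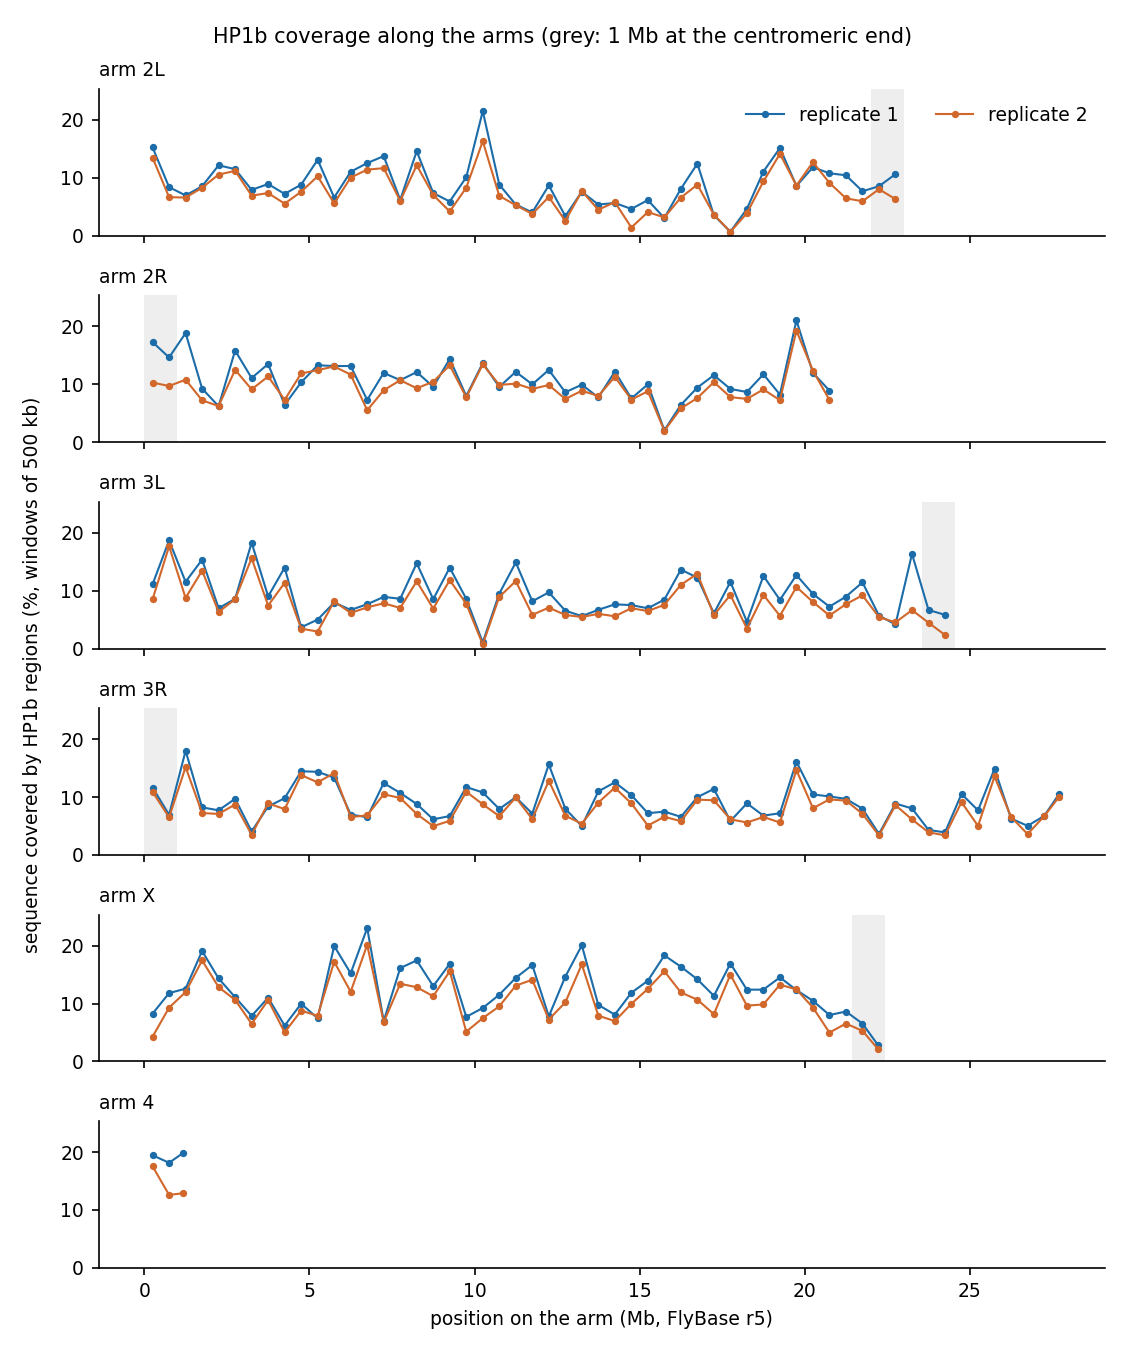
Percent of sequence covered by HP1b regions in windows of 500 kb (y axis) along the 5 major arms and chromosome 4 (x axis, Mb, FlyBase r5) in replicates 1 and 2, with the 1 Mb at the centromeric end of the major arms in grey. The replicates follow each other along the arms, and at the start of 2R replicate 1 lies above replicate 2 (16.0% against 9.99% over the centromeric 1 Mb).

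The strongest reproducible regions lay on the major arms, as did 96.1% of the whole reproducible set (3679 of 3829). All coordinates are FlyBase r5. The region with the highest series-wide score among the 3829 was on 2R at 11733992 to 11736962 (score 3.02), and it ranked 2 in each replicate list, with scores of 3.18 and 3.18. The next lay on X at 19414392 to 19418094 (score 2.79, rank 3 in each replicate), X at 1772582 to 1775652 (score 2.53), X at 16732790 to 16735292 (score 2.47) and 2R at 2548546 to 2552256 (score 2.47). The strongest 3L regions were at 4623652 to 4628728 (score 2.40) and 4552492 to 4555474 (score 2.27). The strongest 2L regions were at 18687792 to 18690676 (score 2.18) and 16485264 to 16488920 (score 2.17), and the strongest 3R regions were at 9226180 to 9230214 (score 2.08) and 12059370 to 12064198 (score 2.03). Of the 20 highest-scoring regions, 5 were on 2L, 5 on 2R, 4 on 3L, 1 on 3R and 5 on X. The whole reproducible set held 636, 718, 702, 833 and 790 regions on these arms. The scores of the 20 ran from 2.03 to 3.02, their median width was 3176 bp, and each overlapped regions that ranked among the top 28 of replicate 1 and the top 43 of replicate 2. The highest-scoring region of each replicate list (4.11 in replicate 1 and 3.87 in replicate 2) was not among those matched to these 20. The set requires a region in both replicates, so high ranks in both are partly built in. The strongest chromosome 4 regions, at 463362 to 467826 (score 1.22) and 86620 to 91190 (score 1.195), ranked 504 and 550 in the reproducible set.

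The widest reproducible regions were not the strongest. The widest lay on 3L at 632642 to 648762 (16121 bp, score 0.63), followed by X at 7590170 to 7605916 (15747 bp, score 1.07), 2L at 22960138 to 22975550 (15413 bp, score 0.86), X at 2189176 to 2202302 (13127 bp, score 0.92) and 2R at 129610 to 142326 (12717 bp, score 1.01). The 2L and 2R regions of this group lie within the 1 Mb at the centromeric end of their arms. The genes at these positions are not named, because an annotation of FlyBase r5 was not used here.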

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

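The local shifts, the arms without the centromeric 1 Mb, the left-out arms, the equal numbers in heterochromatin and the minimum width were chosen after seeing the data; the other alternatives were planned. Of 85 recomputed values, 66 were unchanged (the same direction and side of the threshold or, for the 4 without a test, within the 95% interval of the main value), 10 lost a call, 7 gained one, 1 moved and 1 reversed; the cause was not tested unless named. The replicate overlaps (6 alternatives in each direction), score agreement (2), X (8), 2L (8) and the heterochromatin scaffolds (8) were among the 66 throughout, though the last went from -6.64 percentage points to -2.81 in the whole series-wide list. The counts hold a repeat: for the scaffolds, equal numbers in replicate 2 and replicate 2 alone are the same computation (-6.13 points), since 4633 is its whole list. For the overlaps, random placement and local shifts changed only the null, not the overlap. The series-wide share in both replicates stayed among them under 2 alternatives and moved to 53.0% in regions at least as wide as the narrowest replicate region, by construction, since narrower ones were removed. With regions per Mb, 2L and chromosome 4 stayed only just within the threshold (adjusted permutation p = 0.0495 for both).

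Differences are in percentage points unless said otherwise. Those of single autosomal arms are from the other major arms, X included. In the top-scoring 50% of each list, 2R (0.101) and chromosome 4 (2.63) lost their calls and 3R (-1.01) gained one. In the whole series-wide list 3L (-1.16) lost its call, 3R (-2.54) gained one and the centromeric difference reversed to 6.93. As regions per Mb, 2R (3.78 per Mb) and 3L (-2.90 per Mb) lost their calls and the centromeric difference (-12.0 per Mb, permutation p = 0.00064) gained one. With bins of 250 kb 2R (1.34) and 3L (-1.35) lost theirs. Without the centromeric 1 Mb 2R (1.08) lost its call and 3R (-1.17) gained one, and with 2R left out the centromeric difference (-3.40) gained one. With a single replicate the differences ran from 1.06 to 1.096 for 2R, -1.10 to -0.887 for 3L, -1.20 to -0.627 for 3R and -2.14 to -0.819 for the centromeric end. A correction for assembly gaps and the alternatives for promoters, genomic features and gene lists were not run, since a genome and annotation of release 5 were not used here. No paired analysis was possible because no region list of the Input libraries was analysed here, so the groups were not compared. Depth is unknown, so what it limits cannot be stated.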

Other observations

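The tests of whole-number ratios, of replicate regions on unplaced sequence, of X regions found again at matched score and of the highest-scoring X regions were chosen after the results they bear on had been seen, at least in part. Cover of the distal 1 Mb of the arms, though not of the distal 200 kb, had also been seen before the ends were tested.

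HP1b regions lay in groups along the major arms. In the reproducible set 31.1% of regions had their next neighbour within 5 kb, above all 1000 random placements within the arms (median 22.3%, highest 24.3%). The shares were 36.1% in replicate 1 (highest placement 28.0%) and 33.4% in replicate 2 (highest placement 25.7%). The most densely covered 100 kb window was on 3L at 600001 to 700000, with 44.0% in the reproducible set, 36.1% in replicate 1 and 35.2% in replicate 2. It was followed by 3R at 12000001 to 12100000 (40.4%), X at 1900001 to 2000000 (39.2%) and 2R at 19700001 to 19800000 (38.2%). At the other extreme, 195 of 1203 windows (16.2%) held no reproducible region, in runs of up to 400 kb on 2L at 16900001 to 17300000 and on 3L at 9900001 to 10300000. The windows were chosen after their values were seen.

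HP1 proteins are known from telomeres, and a gathering of HP1b at the distal ends of the arms was tested as a hypothesis. The distal 200 kb of the 5 major arms (10 bins) was covered 7.29% in the reproducible set, against 9.61% elsewhere, a difference of -2.32 percentage points (permutation p = 0.366). The difference was also negative in replicate 1 (-2.19 points, permutation p = 0.366) and in replicate 2 (-2.70 points, permutation p = 0.214). A higher cover of the distal ends was thus not seen in any of these lists; the telomeric repeats themselves were not analysed here.

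The highest scores of the series-wide list belonged to regions that neither replicate list holds. Of the 65 such regions with scores above 2, 48 lay on U and 7 on the heterochromatin scaffolds, with a median width of 1015 bp, while the 23 reproducible regions above 2 all lay elsewhere and had a median width of 3129 bp. Enrichment of unplaced sequence that each replicate shows by itself stays open: 10.8% of the 83 replicate regions above 2 lay on U or heterochromatin (95% Wilson interval 5.81 to 19.3%), against 4.11% of all 9881 replicate regions, but 58 of the 65 regions are narrower than the 1301 bp minimum of the replicate lists, so the comparison decides nothing. A candidate explanation is scores that rest on small whole-number ratios, as few reads or little Input would give. After a single constant was removed, 100% of the 65 scores were log2 of a ratio with a denominator of 10 or less. Of the 23 reproducible ones, 0 were (95% Wilson interval up to 14.3%). The constant was chosen so that the 5 highest distinct scores became whole numbers (12, 11, 10, 9 and 8). All regions with those 5 scores (2, 1, 1, 5 and 10 regions, from the highest score down) are among the 65, so their ratios were fixed by that choice. Only the other scores among the 65 test the explanation. A ratio in lowest terms does not give the read numbers, so the explanation by few reads or little Input stays a hypothesis. Reads shared between repeat copies were not tested.

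Replicate 1 covered more heterochromatin than replicate 2, by 1.73 times on the heterochromatin scaffolds against 1.17 times on the major arms. XHet went the other way (4.22% in replicate 1 and 5.57% in replicate 2, with 4 and 6 regions), and YHet held no region in either. A lower effective threshold on the score in replicate 1 is argued against as the whole cause. Whether regions were called by this score is unknown, so a laxer call by another measure stays open. With 4633 top-scoring regions from each replicate, the scaffolds were covered 4.00% and 2.47%. The ratio of the replicates there was 1.51 times that on the major arms (95% bootstrap interval over bins 1.30 to 1.77). This lay above the bound of 1.2, which was set beforehand for this test. The equal numbers listed as chosen after seeing the data belong to another comparison, that of the scaffolds with the arms. A difference in the precipitation or in the handling of reads from repeats may account for the higher cover in replicate 1 and was not tested. With 2 libraries a replicate and its conditions of preparation are the same thing.

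The higher cover of X was weighed against noise. The labels used here give no sex; a mixture of both sexes would carry fewer copies of X than of autosomes, which could make scores on X noisier. This stays open. Without matching, the shares of replicate 1 regions found again were close (75.1% on X and 77.0% on the autosomal arms, a difference of -1.91 percentage points, 95% interval -4.82 to 1.00), and in replicate 2 they went the other way (87.4% on X and 86.7% on the autosomal arms, a difference of 0.716 points), but X regions score higher, and matching on score was chosen after that value had been seen. At matched score the share of X regions found again differed from that of autosomal regions by -8.85 percentage points in replicate 1, beyond the 5 points set as the bound, and by -3.70 points in replicate 2, whose 95% interval of -5.91 to -1.49 includes that bound. Equal scores on X and on the autosomal arms need not mean equal enrichment, so the matched difference cannot be assigned to noise. Weak regions near the threshold are argued against as the whole cause, since the ratio of X to autosomal cover was 1.63 in the 50% of reproducible regions that scored highest (95% bootstrap interval 1.41 to 1.86), above the 1.33 of the whole reproducible set. This restates the higher scores of X regions, which had been seen, and noise that raises scores on X would raise the ratio too. Gene density, mappability and GC content of the arms were not tested, and a difference between X and autosomes in HP1b binding is a hypothesis that stays open beside them.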
